A study of Mus musculus with 6 samples.

How the data were processed

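Gene expression was measured on 6 single-colour arrays of Cy3-labelled RNA from mouse fetal liver erythroid progenitors. By the labels, the cells were taken at embryonic day 14.5, infected with retrovirus carrying a short hairpin RNA, and kept in culture for 3 days. In 3 samples the hairpin was directed against Exosc8 (shExosc8) and in 3 against luciferase, a gene mouse cells lack (shControl). Each sample was placed in its group by the treatment in its labels, and the replicate number came from its title. No label says whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

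The deposited spot intensity values were produced by the scanner software Agilent Feature Extraction 10.7.3.1, per the file headers, which subtracted a spatial background, detrended each array and replaced values near 0 by surrogates. Flags for spots well above background, saturated, non-uniform or outlying were also written by that software, per the file headers. The deposited table of the whole series holds the same intensity values, equal within 0.01% for all features of all 6 arrays, with no normalization between arrays. It also holds the authors' deposited log2 fold changes and p-values of their comparison, made with limma per the submitters' processing notes, and the normalization behind them is not given in the sources used here. Probe coordinates in the files are on the mouse build mm9, per the file headers.

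Of 62976 features, 3671 control spots were left out. Spots flagged as non-uniform or as population outliers were dropped, spots of 1 probe were averaged on the log2 scale, and 21 of 55681 probes with no usable spot on an array were left out. Names of 27495 of the remaining 55660 probes came from a RefSeq gene table (GRCm38.p6) through the accession in the files without its version, 3549 more had a symbol in that table, and 24616 kept the name in the files. The table was used for names alone. Mpp6, in the list of exosome cofactors, is also the symbol of an unrelated membrane protein in mouse. The cofactor Mphosph6 is a separate entry of that list, so the Mpp6 row should not be read as a cofactor.

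The log2 signal was scaled by subtracting each array's 75th percentile. Because 38.8% of probes were well above background on all 6 arrays, the percentile was taken over those 21615 probes, by a rule fixed before the data were examined. Probes well above background on all arrays of at least 1 group were kept, 24836 in all, and the probe with the highest mean over the 6 arrays stood for each gene. This left 18228 names. Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. In 30 of the 1411 changed genes with several probes, another probe was called in the opposite direction. In only 638 of the 1411 was every probe called in the same direction.

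A probe below background on every array of 1 group gives only a bound, also where another probe of the gene is above it. It is written as "at least" a fold, taken from the bright group's mean against a floor in the dim group, which is per array the higher of the lowest signal among probes well above background and the probe's own signal.

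The 24 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Lists with at least 5 measured genes were tested with camera at its preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, with fry and with camera on ranks. Measured genes are those that passed the filter on dim probes. Among others, 7 of 19 endothelial and stromal, 8 of 20 lymphoid and 27 of 40 interferon genes on the array did. Named genes were the exosome core subunits, the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap and which have a proper symbol, and the 4 members of each list with the smallest p. A further 7 lists were added after the data had been seen and are reported apart. Where a name outside this rule appears, it was chosen after its values were seen. The values of some single genes are not reported here.

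All 6 arrays lay on 1 slide and came from 1 scan, so no slide or scan block could be fitted. The shExosc8 arrays lay in 1 row of the slide and the shControl arrays in the other, so slide row and group cannot be told apart by design. Between 43.1% and 49.3% of non-control spots were well above background on 5 arrays, and 67.3% on shControl replicate 2. The number of arrays limits the precision.

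The limma step was tested on simulated data with the 18228 names and the measured residual spread of the comparison of shExosc8 with shControl. It recovered 37 of 100 genes changed by a log2 of 1 and 0 of 100 changed by 0.5, of which 64 had an unadjusted p under 0.05, with 1 false call. Far fewer genes were changed there than the 5439 called in the data, which makes the adjustment stricter. The recovered shares therefore do not give the power in the data. A list moved by -0.5 was called and 0 other lists were. The genes were simulated without correlation, while the estimated correlation was 0.58 for ribosome biogenesis genes and 0.77 for globins. The simulation therefore does not show how often lists are called falsely in the data. Alternatives covered scaling, background correction, the filter on dim probes, several probes per gene, the replicate block, the variance model, array weights, the threshold and each array left out.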

Results

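The RNA exosome is a multi-subunit complex that degrades and trims RNA from the 3' end, and Exosc8 is 1 of its core subunits. Erythroid progenitors from mouse fetal liver were infected with retrovirus carrying a hairpin against Exosc8 or against luciferase, and RNA was taken after 3 days of culture. By the design text of the series, the cells matured along the red cell lineage in that time, which no array measures. The series title gives the question as which genes depend on Exosc8 in these cells. There were 3 shExosc8 and 3 shControl arrays. Between 25580 and 39936 of 59305 non-control spots were well above background per array. Pairs of arrays of 1 group correlated at r = 0.985 to 0.997 across 21615 probes and pairs from different groups at r = 0.953 to 0.978. Among the shExosc8 arrays, replicate 3 was the closest to the controls.

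Exosc8 was lower in all 3 shExosc8 arrays than in any control. Its probe lies on chromosome 3 at 54535935 to 54536079 of mm9, on the minus strand. The log2 fold change was -1.14 ± 0.16 (SE, n = 3 per group), which left 45.3% of the control level with a 95% interval of 34.4% to 59.6%. Against the control mean, the shExosc8 arrays stood at 40.4%, 40.0% and 57.4% for replicates 1, 2 and 3, and the controls at 98.5%, 97.8% and 103.8%. The adjusted p from limma was 0.00554. An exact permutation test of the 6 values gave p = 0.1, two-sided, the smallest that 3 against 3 can give. With the slide column as a block, which leaves 1 residual degree of freedom, the log2 fold change was -1.03 with an adjusted p of 0.124. Column 1 held only shExosc8 replicate 1 and column 4 only shControl replicate 3. Those arrays do not bear on the group difference of that fit.

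**Figure D1:**
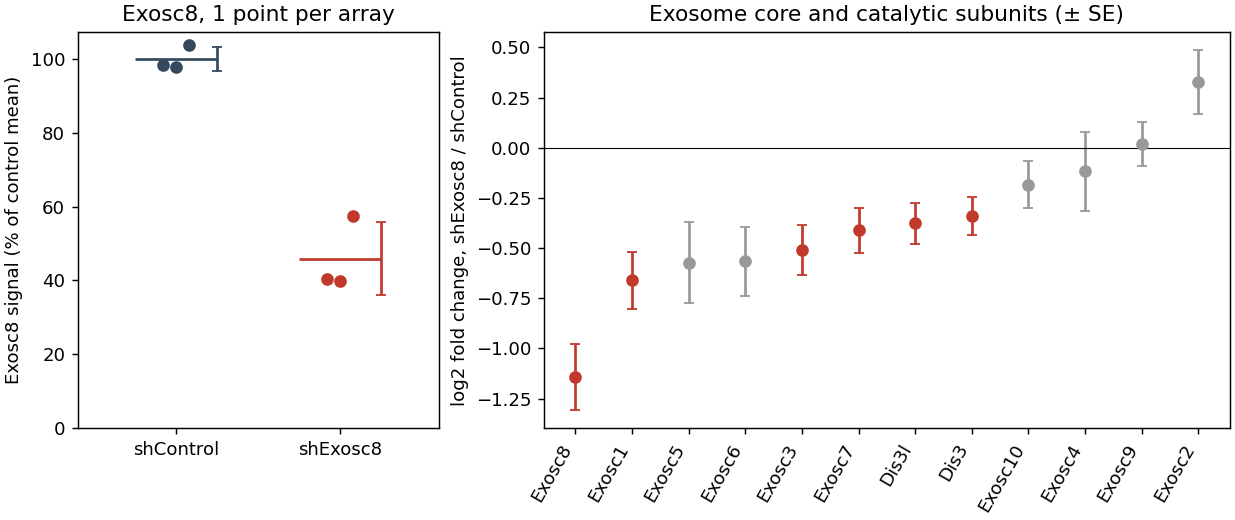
Left, Exosc8 signal of each array as a percent of the control mean, with the mean as a line and the SD as a bar (3 arrays per group). Right, log2 fold change of the 12 exosome core and catalytic subunits with SE bars, in red for the 6 that passed the threshold, with Exosc8 lowest at -1.14.

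Other exosome subunits fell with Exosc8. Of the 12 core and catalytic subunits measured, 6 fell and 0 rose, and adjusted over the list alone 8 fell. Exosc1 fell by 0.66 ± 0.14 on the log2 scale (SE), Exosc3 fell by 0.51 ± 0.12 and Exosc7 fell by 0.41 ± 0.11. The catalytic ribonuclease Dis3 fell by 0.34 ± 0.09 and its cytoplasmic paralog Dis3l fell by 0.38 ± 0.10. The values of Exosc5 (-0.57, adjusted p = 0.075), Exosc6 (-0.57, adjusted p = 0.0517), Exosc10 (-0.19), Exosc4 (-0.12), Exosc9 (0.02) and Exosc2 (0.33) did not pass. The other of 2 Exosc10 probes was called down when each probe was tested on its own. The Exosc2 probe had a mean log2 signal of 18.8 in shControl, against 15.3 for Exosc5, and whether it measures Exosc2 alone was not tested. Without shExosc8 replicate 3 both Exosc5 (adjusted p = 0.0228) and Exosc6 (adjusted p = 0.00493) passed, as did Exosc5 with normexp and quantile normalization (adjusted p = 0.0252) and Exosc6 with median centring (adjusted p = 0.0415). With 1 array left out in turn, each of the 5 fallen subunits besides Exosc8 lost its call for 3 to 5 of the 6 arrays and stayed below 0. Among 19 exosome cofactors 6 fell and 0 rose, the same counts as adjusted over the list alone, among them Mphosph6 at -0.82, Zcchc8 at -0.85, the scaffold Ttc37 at -0.54 and Zcchc7 at -0.47. Camera called both lists as shifted down, at adjusted p = 0.0127 for the subunits and 0.0181 for the cofactors. With an estimated correlation the adjusted p was 0.381 and 0.332. The subunit list holds the target of the hairpin, and without Exosc8, an alternative chosen after seeing the data, 5 of 11 subunits fell (median -0.38, adjusted p = 0.0291, and adjusted p = 0.401 with an estimated correlation). Without shControl replicate 3 the cofactors lost their call (median -0.21, adjusted p = 0.0643), and with 1 array left out in turn Zcchc8 and Zcchc7 lost theirs for 5 of 6 arrays, Ttc37 for 3 and Mphosph6 for 1.

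Knockdown of Exosc8 went with changes in a large part of the measured transcripts, with the large changes mostly rises. Of 18228 names tested, 5439 changed, 2923 upward and 2516 downward. At least 2-fold changes numbered 1845 up and 351 down. Among 12757 names in the reference gene table, 4152 changed, 2097 upward and 2055 downward. The 3 arrays of 1 group lay all above or all below the other group for 51.6% of names, where chance gives 10%. In the authors' deposited table, 1980 non-control spots had an adjusted p under 0.05, 1679 of them higher, and 5436 of the 5439 changed genes had the same direction there. An adjusted p under 0.05 in the authors' deposited table was found for 1331 of the 5439, and that of Exosc8 there was 0.073.

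The share of rises among changed genes was 53.7%. It was 37.1% when the percentile was taken over all probes, 67.0% with normexp and the 75th percentile, and 18.0% on values not normalized between arrays. The count was 2343 without shExosc8 replicate 1, 3028 without replicate 2 and 8469 without replicate 3, and 2465, 3290 and 2608 without shControl replicates 1, 2 and 3. Without shExosc8 replicate 3 and shControl replicate 2 together, an alternative chosen after seeing the data, 7401 genes changed. With the slide column as a block 537 changed, in a fit where shExosc8 replicate 1 and shControl replicate 3 do not bear on the group difference.

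Among the 8 largest fitted rises, whose order is uncertain because most had control signal below background, were Tmem140 at 5.58 ± 0.29 on the log2 scale, above background on all 3 control arrays, and Mycn, a transcription factor of the Myc family, at 6.15 ± 0.34 with 1 of 3 above. The matricellular protein gene Ccn4 was at least 21.1-fold higher, Cnrip1 at least 23-fold and Ephx4 at least 13.7-fold, since no control array measured them above background. Serpina3f was at 5.52 and Nyx at 5.25, each above background on 1 of 3 control arrays. The probe of Dusp13 was at least 30.7-fold higher, above background on no control array. The largest fitted falls were those of Chga, which encodes chromogranin A, at -4.81 ± 0.33, and Mgarp, which encodes a mitochondrial protein, at -4.16 ± 0.16. Ndufa4l2 fell by 2.95 ± 0.77 and Paqr6 fell by 2.69 ± 0.17, and the call of Ndufa4l2 was lost for 3 of 6 arrays left out in turn. Gipr was at least 4.04-fold lower, Sh2d4a at least 5.63-fold, Cpne6 at least 2.94-fold and Tfap2c at least 2.38-fold.

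**Figure D2:**
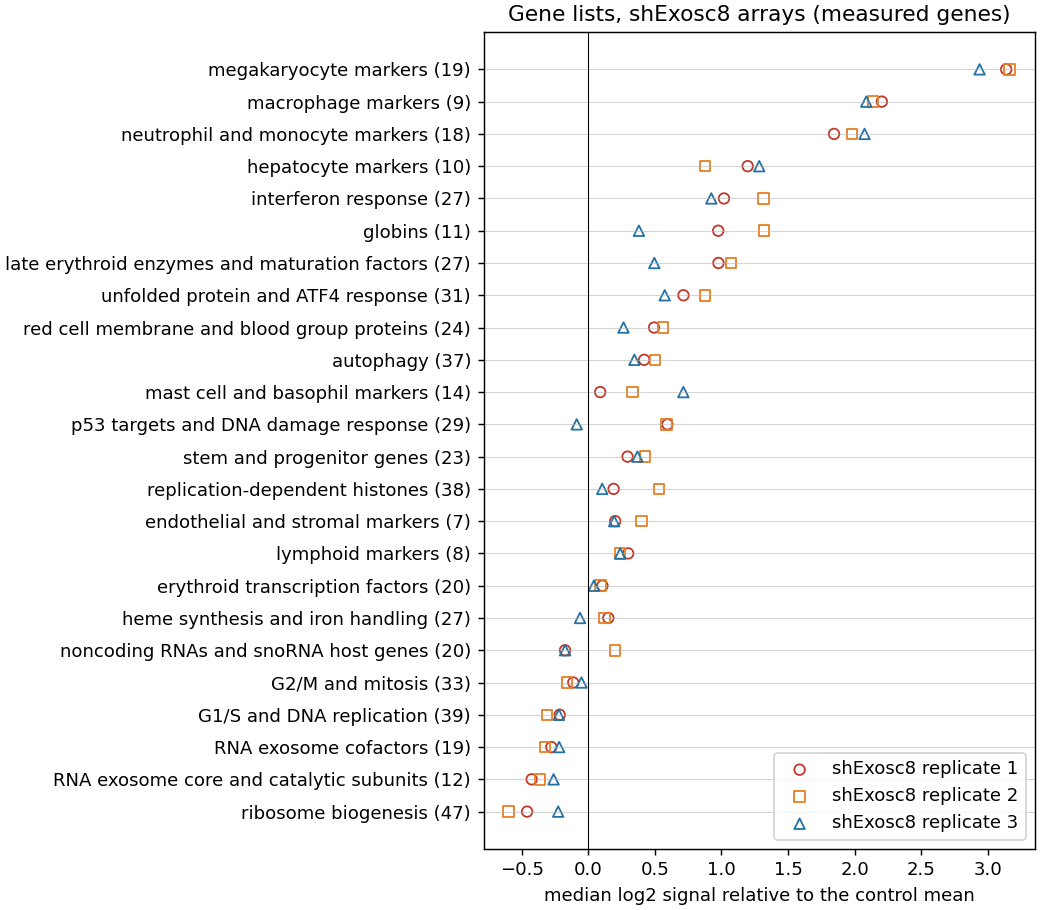
Median log2 signal of each of the 24 gene lists in the 3 shExosc8 arrays relative to the mean of the 3 control arrays, with the number of measured genes in brackets and 1 symbol per array. Megakaryocyte markers stand highest, at 3.14, 3.16 and 2.94 in replicates 1, 2 and 3, and ribosome biogenesis genes at -0.46, -0.60 and -0.23.

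In the late erythroid, red cell membrane and globin lists more genes rose than fell, and many did not pass. Of 27 late erythroid enzymes and maturation factors 14 rose and 1, the erythropoietin receptor gene Epor, fell, and adjusted over the list alone 19 rose and 2 fell. Bpgm, which makes the haemoglobin ligand 2,3-bisphosphoglycerate, rose by 2.12 ± 0.21 on the log2 scale (SE), the ubiquitin-conjugating enzyme gene Ube2o by 2.16 ± 0.26, the ubiquitin ligase gene Trim58 by 1.83 ± 0.18 and the exportin gene Xpo7 by 2.47 ± 0.30. Of 24 red cell membrane and blood group genes 9 rose and 0 fell, the same as adjusted over the list alone, including Epb41 (1.82) and Epb42 (1.72). The water channel gene Aqp1 (0.48) rose as well and stood at -0.019 on values not normalized between arrays. Of 11 globin genes, counted with the chaperone gene Ahsp, 4 rose and 0 fell, and 5 rose adjusted over the list alone. Hbq1a rose by 3.77 ± 0.46, Hbq1b by 2.34, Hbb-bs by 1.13 and Hbb-b2 by 0.99, and near-identical globin copies can share probe signal. Camera's adjusted p was 2.42e-06 for late erythroid genes, 4.05e-05 for membrane genes and 0.00122 for globins. With an estimated correlation the adjusted p was 0.431 for each. Without shControl replicate 3 the list medians moved from 0.80 to 0.53, from 0.40 to 0.26 and from 0.99 to 0.54, and Hbb-b2 and Aqp1 each lost their call for 4 of 6 arrays left out in turn and Hbb-bs for 1 (adjusted p = 0.0501).

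Heme and iron genes and erythroid transcription factors moved in both directions. Of 27 heme and iron genes 6 rose and 4 fell, and 7 rose and 5 fell adjusted over the list alone. Alas2, the rate-limiting enzyme of erythroid heme synthesis, rose by 1.67 ± 0.25 and the mitochondrial carrier gene Slc25a39 by 1.39, while transferrin receptor 2 (Tfr2) fell by 1.28 ± 0.15. The iron-sulfur scaffold gene Iscu rose by 0.91. The other falls were those of Steap3 (-0.95), Hebp1 (-0.67) and the heme exporter gene Flvcr1 (-0.37). Of 20 erythroid transcription factors 3 rose and 3 fell, and 5 rose and 4 fell adjusted over the list alone. Nfe2 rose by 1.13 ± 0.13, Foxo3 by 1.38 and E2f2 by 1.07, while Ldb1 fell by 1.14 ± 0.10, Bcl11a fell by 0.60 and E2f4 fell by 0.54, the last 2 losing their call for 5 and 4 of 6 arrays left out in turn. Gata1, outside the rule for named genes, was at 0.06 with an adjusted p of 0.726. Camera called neither list, with adjusted p of 0.372 and 0.776.

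Markers of other blood cells rose alongside part of the erythroid genes. Of 19 megakaryocyte markers 18 rose and 0 fell, and 19 rose adjusted over the list alone. The platelet glycoprotein gene Gp1bb was 15.2-fold higher (log2 3.92 ± 0.14, SE), the integrin gene Itga2b 11.4-fold, P-selectin (Selp) 8.24-fold and von Willebrand factor (Vwf) 7.66-fold. Of 18 neutrophil and monocyte markers 16 rose and 0 fell, and 17 rose adjusted over the list alone, including the calprotectin subunit gene S100a8 (2.17 ± 0.13), Lcn2 (2.15), Ly6c1 (2.16) and the granulocyte factor gene Cebpe (2.14). Of 22 macrophage markers on the array, only 9 passed the filter on dim probes. Of these 7 rose and 0 fell, and 8 rose adjusted over the list alone. Those that rose included the lysozyme genes Lyz1 (2.14) and Lyz2 (2.27), Tyrobp (2.27) and Ctss (2.52). With no filter the median of the macrophage list was 0.76, against 2.14. Camera's adjusted p was 6.89e-16, 1.12e-09 and 1.66e-05 for these lists, and with an estimated correlation the adjusted p was 0.28, 0.28 and 0.381. All 19 measured megakaryocyte markers, all 18 neutrophil and monocyte markers and 8 of 9 macrophage markers were well above background on every control array.

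Of 14 mast cell and basophil markers 6 rose and 0 fell, the same as adjusted over the list alone. Carboxypeptidase A3 (Cpa3) rose by 3.25 ± 0.28, Cma1 by 3.25 and Hdc, which makes histamine, by 1.27. Cyp11a1 was at least 6.49-fold higher. Of 21 hepatocyte markers on the array, only 10 passed the filter on dim probes. Of these 4 rose and 0 fell, and 5 rose adjusted over the list alone. Those that rose included the apolipoprotein gene Apoc1 (1.91 ± 0.41), Fgb (1.83, above background on 1 of 3 control arrays), Ahsg (1.69) and the transferrin gene Trf (1.78). With no filter the median of the hepatocyte list was 0.56, against 1.38. With 1 array left out in turn, Apoc1, Ahsg and Trf lost their call for 4 of 6 arrays and Fgb for 3. Of 23 stem and progenitor genes 10 rose and 2 fell, and 10 rose and 4 fell adjusted over the list alone, with Mycn at 6.15, the homeobox gene Meis1 at 3.36 ± 0.32, Cd9 at 3.00 and Csf2rb at 1.86. The receptor gene Kit (-1.16) and Myb (-0.89) fell. For these lists camera gave an adjusted p of 0.0291, 0.00731 and 0.0404, and with an estimated correlation the adjusted p was 0.431, 0.28 and 0.515. Without shExosc8 replicate 3 the hepatocyte list (1.13, adjusted p = 0.0564) and the stem and progenitor list (0.35, adjusted p = 0.212) lost their calls, the latter also without shControl replicate 1 (0.24, adjusted p = 0.0545) or 2 (0.14, adjusted p = 0.136), and the median of the mast cell list was 0.067 without shControl replicate 1, against 0.26. Of 7 endothelial and stromal markers 2 rose (Sparc at 2.69 and Pecam1 at 0.88) and 1 fell (Pdgfrb at -1.29), the same as adjusted over the list alone, and Kdr was at 0.26. With 1 array left out in turn, Pecam1 lost its call for 4 of 6 arrays, and Vpreb3 for 5. Of 8 lymphoid markers 1 rose, Vpreb3 at 1.64 with 2 of 3 control arrays above background, also when adjusted over the list alone, while Nkg7 (0.34), Cd79b (1.25) and Cd3e (0.19) did not pass. Camera called neither, with adjusted p of 0.218 and 0.156.

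Ribosome biogenesis genes and some DNA replication genes fell. Of 47 ribosome biogenesis genes 20 fell and 0 rose, and 35 fell adjusted over the list alone. The median log2 fold change was -0.46. Nop10, a protein of box H/ACA particles, fell by 0.60 ± 0.11, the RNA polymerase I subunit gene Polr1a fell by 0.49 ± 0.10, Utp20 fell by 0.76 ± 0.17 and Rcl1 fell by 0.56 ± 0.13. Of 39 G1/S and replication genes 6 fell and 1 rose, and adjusted over the list alone 4 fell and 0 rose. The kinase genes Cdk6 (-0.89) and Cdk4 (-0.46), the replication licensing gene Cdc6 (-0.61) and Gins2 (-0.76) fell, and the ribonucleotide reductase gene Rrm2 rose (0.85). With 1 array left out in turn, Cdk6 lost its call for 0 of 6 arrays, Cdc6 for 1, Nop10 for 2, Utp20 and Polr1a for 3, Gins2 for 4 and Rcl1 and Cdk4 for 5. The lists had a camera adjusted p of 1.94e-07 and 0.00187, and with an estimated correlation the adjusted p was 0.431 and 0.439. Of 33 G2/M genes 2 fell, Bub1b at -0.52 and Hmmr at -0.52, which lost their call for 2 and 4 of 6 arrays left out in turn, and 0 did when adjusted over the list alone, while Anln (-0.33) and Nusap1 (0.37) did not pass. Camera did not call that list, with an adjusted p of 0.356.

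In the unfolded protein, interferon, autophagy and p53 lists more genes rose than fell, and many did not pass. Of 31 unfolded protein and ATF4 response genes 18 rose and 0 fell, the same as adjusted over the list alone. Atf3 rose by 3.82 ± 0.30, the C/EBP homologous protein gene Ddit3 by 2.55, Cebpg by 2.01 and the co-chaperone gene Dnajb9 by 1.98. Of 27 interferon response genes 15 rose and 2 fell, and 15 rose and 3 fell adjusted over the list alone. Oasl2 rose by 5.09 ± 0.35, Rsad2 by 4.65, Isg15, a ubiquitin-like protein gene, by 3.31 and Igtp by 2.55, while Eif2ak2 fell to 35.0% and Bst2 to 49.9% of the control level. Of 37 autophagy genes 17 rose and 4 fell, and 20 rose and 7 fell adjusted over the list alone, including the cargo receptor gene Sqstm1 (2.46 ± 0.14), Pink1 (2.00), the initiating kinase gene Ulk1 (1.41) and Optn (1.34). The falls were those of Tfeb (-1.06), Vps18 (-0.78), Wipi1 (-0.56) and Atg10 (-0.35). Of 29 p53 target and DNA damage genes 10 rose and 2 fell, and 12 rose and 3 fell adjusted over the list alone, with Gadd45a at 3.06 ± 0.37, Bbc3 at 2.41, Sesn2 at 1.75 and the cyclin-dependent kinase inhibitor gene Cdkn1b at 1.57, while Tnfrsf10b fell (-0.73) and Cdkn2a was at least 1.66-fold lower, above background on no shExosc8 array. Camera's adjusted p was 1.07e-05, 0.000958, 0.00207 and 0.0259 in that order, and with an estimated correlation the adjusted p was 0.28, 0.431, 0.431 and 0.6. With normexp and quantile normalization the interferon list median was 0.44 against 1.11. The median of the p53 list was 0.59 in shExosc8 replicates 1 and 2 and -0.09 in replicate 3. It lost its call without shExosc8 replicate 1 (0.14, adjusted p = 0.0531) or 2 (0.11, adjusted p = 0.0648) or shControl replicate 2 (0.30, adjusted p = 0.0614). The call of the p53 list was also lost with fry (adjusted p = 0.138). With camera it was lost with no filter on dim probes (adjusted p = 0.0545) and with the slide column block (adjusted p = 0.0543).

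Of 38 replication-dependent histone genes 11 rose and 0 fell, the same as adjusted over the list alone, including H2bc4 (2.60 ± 0.32), H2aw (2.57), H2bu2 (2.11) and H2bc8 (1.88). The camera adjusted p was 0.000516, and with an estimated correlation the adjusted p was 0.537. With fry the call was lost (adjusted p = 0.102), and the list median of 0.28 was 0.13 without shExosc8 replicate 2, 0.11 with quantile normalization and 0.093 with normexp and quantile normalization. Of 20 noncoding RNA and snoRNA host genes 2 rose and 4 fell, the same as adjusted over the list alone. The nuclear RNAs Neat1 (3.02 ± 0.38) and Malat1 (1.67 ± 0.41) rose, while Snhg3 (-0.44), Snhg12 (-0.59), Snhg7 (-0.83) and Dancr (-0.41) fell. Malat1 lost its call for 4 of 6 arrays left out in turn, Snhg3 for 5 and Snhg12 for 3. The median of that list was -0.12 and its mean 0.07, and camera did not call it (adjusted p = 0.706).

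Camera called 18 of the 24 lists, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05 and the smallest adjusted p was 0.28. Fry, which asks whether a list's genes move 1 way on balance without comparing them with other genes, called 18 as well, but not the same 18. It did not call the p53 and histone lists. It called the endothelial (fry adjusted p = 0.0311) and lymphoid lists (fry adjusted p = 0.0266), which camera did not. The median of all genes was -0.06, and it was -0.21 with the percentile over all probes, -0.11 with median centring and -0.12 with quantile normalization. With normexp it was -0.09 after quantile normalization and 0.04 after scaling to the 75th percentile. It was -0.56 on values not normalized between arrays. Those last values put every gene -0.50 from its main value, so the medians of the membrane (-0.10), autophagy (-0.10), stem and progenitor (-0.14), histone (-0.21), mast cell (-0.24) and p53 lists (-0.28) were below 0 by construction, and relative to the median of all genes 0 of these lists turned sign.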

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

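The tests of the number of changed genes and shifted lists against other groupings, of the share of erythroid cells, of the share of megakaryocytes and of replicate 3 by cell type list were chosen after those results were seen.

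Spike-in control probes, which the comparisons do not use, had a median log2 difference of 0.31 between shExosc8 and shControl after scaling and of -0.19 before, over 7 probes above background on all 6 arrays. The groups overlapped: against the control mean, the shExosc8 arrays stood at 0.19, 0.90 and -0.12 and the controls at -0.16, -0.19 and 0.37 for replicates 1, 2 and 3. The difference was 0.037 without shExosc8 replicate 2 and 0.52 without shExosc8 replicate 3.

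The real grouping of the 6 arrays gave 5439 changed genes with limma, and the highest of the other 9 splits gave 0, with at most 1549 genes at an unadjusted p under 0.05. It gave 18 shifted lists with camera, and the other 9 splits gave 5 to 15, so camera at its preset correlation called lists under every grouping. In each case 1 of 10 splits reached the real value, and 10 splits are too few for a share under 0.05.

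Megakaryocyte, neutrophil and macrophage markers rose together. A lower share of erythroid cells, with the mix of other cells unchanged, would raise the markers of those cells alike. The median of megakaryocyte markers exceeded that of mast cell, endothelial and lymphoid markers by 2.89 (bootstrap 95% interval 2.32 to 3.32, resampling genes, not arrays). Those 3 lists were chosen after their low medians (0.26, 0.26 and 0.25) had been seen, so a gap was known beforehand. Neutrophil (1.87), macrophage (2.14) and hepatocyte markers (1.38), which rose more, were left out. The lists of other cells therefore did not rise alike, but the size of this gap reflects that choice. A lower erythroid share with a changed mix stays open. The mast cell list was itself split, with quartiles of -0.20 and 2.61. The spike-in probes differed between the slide rows by a median of 0.31 in absolute log2, at most 0.38, under the limit of 0.5 set before the result. Without shExosc8 replicate 3 the median was 0.52, above that limit. Both are far below the 3.11 of the megakaryocyte list, a yardstick chosen afterwards. They argue only against a row effect that the 7 spike-in probes would share as the whole cause. Anything else that went with the row cannot be told apart from the group by design. That 94.7% of the measured megakaryocyte markers rose, 18 of 19, restates the pattern and decides nothing about a larger share of megakaryocytes. That explanation stays open, as do a rise within erythroid cells and a direct effect of Exosc8 loss.

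Ribosome biogenesis genes fell. Relative to all genes, their median was between -0.46 and -0.33 under the 3 scalings that do not move an array by 1 constant, the only ones that could change it, which argues against the choice of scaling as the cause. After a trend of the fold change on mean signal was removed, the list median was -0.33 (95% interval -0.38 to -0.29) against -0.46 before. The interval resampled genes, whose estimated correlation was 0.58, so it leaves out the spread between arrays. In these arrays such a trend did not account for the whole fall. A biological response to Exosc8 knockdown is a hypothesis that both tests leave open. Slide row cannot be told apart from the group by design.

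On a scale from the controls at 0 to shExosc8 replicates 1 and 2 at 1, replicate 3 stood at a median of 0.50 for rising and 0.69 for falling genes, but its medians of neutrophil and monocyte (2.07 against 1.85 and 1.98), mast cell (0.71 against 0.089 and 0.33) and hepatocyte markers (1.28 against 1.20 and 0.88) were higher than theirs. Compression by background on a dim array would spare bright genes. In the 729 brightest changed genes, however, the slope of replicate 3 on replicates 1 and 2 was 0.73 (95% interval 0.71 to 0.74, resampling genes, not arrays). Fewer knocked-down cells could give 1 mixing share for every gene, and the share from rising genes minus that from falling genes was -0.20. The limit of 0.15 set before the result proved too tight to exclude this, because another replicate gave a gap of 0.22 in the same calculation. The share from markers of other blood cells minus that from erythroid markers was 0.28 (95% interval 0.17 to 0.39, resampling genes, not arrays). In the other replicates this difference was as far from 0 as -0.23, so fewer knocked-down cells stay open as an explanation.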

How the results depend on the processing

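The slide column block, the omission of both arrays in doubt and the exosome list without Exosc8 (median -0.38, adjusted p = 0.0291, call kept) were chosen after seeing the data. In the slide column block, shExosc8 replicate 1 and shControl replicate 3 were each alone in their column. The group differences of that block rest on the other arrays, so a column effect cannot be told apart from the loss of these arrays. Exosc8 kept its direction under every alternative run and its call under all but the slide column block (-1.03, adjusted p = 0.124, 1 residual degree of freedom). Leaving out 1 array at a time gave -1.32 to -1.06. The slide as a fixed or random block was not run, because there was 1 slide and 1 scan, and Exosc8 has 1 probe, so its probes were not compared. The number of changed genes was 2343 to 8469 with 1 array left out, with 1654 to 4205 rising and 689 to 4264 falling. It was 9167 (1648 rose, 7519 fell) on the deposited values not normalized between arrays, 1815 (1449 and 366) with no filter on dim probes, 12830 (5727 and 7103) with array weights, whose estimation stopped before convergence, and 537 (496 and 41) with the slide column block. Falls numbered 4490 with the percentile over all probes and 1613 with normexp and the 75th percentile. At an adjusted p under 0.05 with a log2 fold change of at least 1 there were 2196 (1845 and 351), at 0.01 there were 1802 (1375 and 427), and at 0.10 there were 4066 falls. The threshold counts follow from their construction, and the cause of the others was not tested.

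Whether replicate numbers pair the samples was not settled. Deviations from the group means correlated at 0.04, 0.22 and 0.30 for numbers 1, 2 and 3, and at -0.26 to 0.17 between unlike numbers. Not every sample correlated best with its own number. Deviations within a group sum to 0, so these values depend on each other and cannot decide it. With the replicate number as a block, 5633 genes changed, and the stem and progenitor (0.36, adjusted p = 0.0885) and mast cell lists (0.26, adjusted p = 0.0688) lost their calls.

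The stem and progenitor list lost its call with normexp and the 75th percentile (0.38), with no filter on dim probes (0.36), on probes above background on all 6 arrays (0.36), with camera on ranks (0.36) and without both arrays in doubt (0.13), where the hepatocyte list lost it too (0.91). The p53 list lost its call with no filter (0.22), with fry (0.22) and with the slide column block (0.10). The histone list lost it with fry (0.28). The endothelial list gained one with no filter (0.56) and with fry (0.26), and the lymphoid list with every probe on its own (0.32) and with fry (0.25). With an estimated correlation all 18 calls ended, at unmoved medians of -0.39 for exosome subunits, -0.24 for cofactors, 0.99 for globins, 0.40 for membrane genes, 0.80 for late erythroid genes, 0.36 for stem and progenitor genes, 0.39 for autophagy, 0.22 for p53 targets, -0.28 for G1/S genes, -0.46 for ribosome biogenesis, 0.28 for histones, 1.11 for interferon genes, 0.67 for the unfolded protein response, 1.87 for neutrophil, 2.14 for macrophage, 3.11 for megakaryocyte, 0.26 for mast cell and 1.38 for hepatocyte markers. With 1 array left out, the lists that lost a call ranged from 0.14 to 0.45 (stem and progenitor, without shExosc8 replicate 3 or shControl replicate 1 or 2), 0.11 to 0.59 (p53, without shExosc8 replicate 1 or 2 or shControl replicate 2), 1.13 to 1.66 (hepatocyte, without shExosc8 replicate 3) and -0.31 to -0.19 (cofactors, without shControl replicate 3). Lists that kept their call in the same run moved by over 1.5 times without shControl replicate 3 (globins to 0.54, membrane genes to 0.26, late erythroid genes to 0.53, interferon genes to 0.71, mast cell markers to 0.45, p53 targets to 0.11), without shControl replicate 1 (mast cell to 0.067, p53 to 0.42) or 2 (mast cell to 0.15), and without shExosc8 replicate 2 (histones to 0.13) or 3 (p53 to 0.59). So did interferon (0.44), hepatocyte (0.72), macrophage (1.35), globin (0.58), histone (0.093) and mast cell lists (0.17) with normexp and quantile normalization, interferon genes with normexp and the 75th percentile (0.67) or on probes above background on all 6 arrays (0.62), histones with quantile normalization (0.11) or array weights (0.13), macrophage (0.76), mast cell (0.63) and hepatocyte markers (0.56) with no filter, mast cell markers with averaged probes (0.47), p53 targets with every probe on its own or array weights (0.33 each), globins (0.49), membrane (0.23), late erythroid (0.49) and mast cell lists (0.73) with the slide column block, and p53 (0.43) and mast cell lists (0.14) without both arrays in doubt. The percentile over all probes moved all lists and the median of all genes by 1 constant, which took cofactors to -0.38, G1/S genes to -0.43, autophagy to 0.25, stem and progenitor genes to 0.22, p53 targets to 0.070, histones to 0.14, mast cell markers to 0.12 and membrane genes to 0.26. Aqp1 changed sign on the values not normalized between arrays (-0.019). Of the 118 named genes besides Exosc8, 36 lost their call with no filter on dim probes, 64 with the slide column block, 13 with normexp and the 75th percentile, and between 17 and 32 without shExosc8 replicate 1 or 2 or any 1 of the 3 shControl arrays.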

Other observations

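The test of lincRNA region probes and that of hypoxia-inducible genes were written down before their results were seen, and the 7 gene lists here were added after the main results.

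NF-kappaB targets rose, 8 of 13 measured and 0 fell, with 8 up and 1 down adjusted over the list alone (camera adjusted p over the 7 lists = 0.00895, adjusted p = 0.295 with an estimated correlation). Relb was 10.6-fold higher, Bcl3 7.25-fold and the inhibitor gene Nfkbia 3.62-fold. Of 18 NRF2 antioxidant genes 7 rose and 2 fell, and 8 rose and 2 fell adjusted over the list alone, with Ugdh at 2.81 ± 0.27 on the log2 scale and the glutathione synthesis gene Gclc at 1.40 ± 0.15, while Gstm5 (-0.81) and Tkt (-0.50) fell. Of 12 class I antigen presentation genes 2 rose, H2-D1, 2.09-fold higher and H2-T23, 3.02-fold higher, and 4 fell, Psme1 at -0.91, Psme2 at -0.65, Tap2 at -0.40 and B2m at -0.46, the same counts as adjusted over the list alone.

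Most genes of cholesterol synthesis, the proteasome and the respiratory chain did not pass. Of 20 cholesterol synthesis genes 3 rose (Idi1 at 0.54, Sqle at 0.46 and Hmgcs1 at 0.39) and 1 fell (Scd2 at -0.63), and 1 and 0 did adjusted over the list alone. Of 31 proteasome subunits Psmd8 rose (0.33) and Psmd7 fell (-0.49), and of 34 respiratory chain subunits Ndufb9 rose (0.36) and 2 fell, among them Ndufb6 (-0.32), with 0 calls in either list adjusted over the list alone. Camera's adjusted p was 0.293 for NRF2 genes, 0.526 for antigen presentation, 0.498 for cholesterol synthesis, 0.242 for the proteasome and 0.0873 for the respiratory chain. Fry, which does not compare a list with other genes, gave an adjusted p of 0.0189, 0.202, 0.205, 0.0451 and 0.00756 for the same lists, and 0.00256 for NF-kappaB targets.

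The hypothesis that hypoxia-inducible genes fell together, as Mgarp and Ndufa4l2 did, was left undecided. Without those genes, the median of the 26 measured members was -0.53, with a camera adjusted p of 0.225 an adjusted p of 0.108 with fry and an adjusted p of 0.631 with an estimated correlation. P4ha2 (-1.67), Fam162a (-0.77) and Ero1a (-0.67) were among 7 that fell, while Ndrg1 (2.83) and Bnip3 (1.80) were among 3 that rose, and adjusted over the list alone 8 fell and 4 rose.

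The hypothesis that loss of the RNA exosome raises long intergenic noncoding transcripts was not decided either. Of 4453 probes for such regions 632 rose and 414 fell. Their median lay 0.09 above that of probes matched on mean signal, higher than in all of 10000 matched probe lists, but below the 0.1 set beforehand, and 2 of the other 9 splits of the arrays gave a larger difference, at most 0.0943 against 0.0853.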
